A study of Mus musculus with 2 samples.

How the data were processed

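Chromatin immunoprecipitation followed by sequencing was performed on BMiFLT3(15-3) cells, a mouse pro-B-cell line from a B-cell-precursor leukaemia that had been transduced with Runx1 fused to ERt2. Runx1 is the DNA-binding subunit of core-binding factor, and the fusion moves to the nucleus when tamoxifen is added. The data comprise 2 libraries. The first was precipitated with a rabbit antibody raised against a C-terminal peptide of Runx1, and the second with rabbit IgG as the background control. Per the labels' protocols, cells received either 0.2 µM tamoxifen or ethanol for 24 h before extraction, and library fragments of 350 to 550 bp were isolated. The labels do not say which of these treatments each library had.

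The file analysed is a list of peaks, each with a chromosome, a start, an end and a score, made by the authors from the Runx1 library and the IgG library together, per the file header. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.8, MACS 1.4.01 and the mouse genome build mm9, with no settings. The file header and the peak names also point to MACS. The peak score is the authors' deposited value from the caller. Its scale is not stated. The lowest value lies just above 50. That is what a score of -10 times the base-10 logarithm of a peak p-value would give with a limit of 1e-05 on that value. The scale was inferred from this alone, and the score was compared only between peaks of this list. Medians and their differences are in the caller's score units, and a calculation with halved scores further assumes that the score is proportional to the evidence. The list gives no fold enrichment, false discovery rate, summit or read number. The depth of either library is therefore unknown here, no threshold could be tied to depth, and weakly bound sites may be missing from the list. Duplicate removal, the tag shift and any control scaling are not given in the sources used here.

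Positions are mm9 and are printed counting from 1. The gene table at hand describes GRCm38.p6, a later build, and the last peak on chromosome 1 ends at 196822080, beyond the last gene of that chromosome in the table. Coordinates were not converted between builds. Peaks were therefore not assigned to genes, transcription start sites, exons, introns or repeats, and motifs were not searched. The 14 gene lists and the motif, promoter and repeat comparisons fixed before the data were examined were not run, and the coordinate-only plan fixed with them was used. Under that plan the regions named are the 10 highest-scoring peaks and the 5 largest clusters, with ties in size broken by the highest score. From the gene table only the number of protein-coding genes per chromosome was taken, without coordinates.

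Each interval was counted as 1 peak. Peak number per Mb was taken over the span from the first to the last peak of each chromosome, since mm9 chromosome lengths were not used here, with exact Poisson 95% intervals on the number of peaks. A share of peaks has a Wilson 95% interval. These intervals cover counting error only and treat peaks as independent, which the clustering of peaks makes too narrow. A cluster was defined as 3 or more peaks on chromosomes 1 to 19 or X whose neighbouring midpoints lay within 20 kb. Its number was compared with 1000 random placements, in which the midpoints of each chromosome were redrawn uniformly between its first and last peak. With 1 library per arm there was no replicate, so no p-value for the immunoprecipitation is given, and every comparison below describes this one list. The counting of clusters was checked on simulated data. In these, 200 of 200 planted clusters were found. Of 100 simulated uniform lists of the same size, 97 fell within the 95% range of the placements. The planted clusters met the 20-kb rule by construction, and the uniform lists were drawn as the placements were. Both results therefore check only that the counting works, and say nothing about the real list.

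Alternatives fixed before the data were examined were a score of at least 100, the upper part of the list by score, chromosomes 1 to 19 and X alone, leaving out peaks wider than 5 kb, merging intervals within 500 bp, and cluster distances of 10 and 50 kb. Merging within 2 kb, and the X density after either merging, were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.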

Results

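The series mapped binding of the transcription factor Runx1 in early B-cell progenitors. The comparison was of 1 library precipitated with anti-Runx1 against 1 library precipitated with IgG, both from the pro-B-cell line BMiFLT3(15-3) carrying Runx1-ERt2. In the peak list made from these libraries, 6792 regions were called enriched for Runx1 over IgG. The list does not tell binding of the cells' own Runx1 from binding of the introduced fusion. The 6792 regions covered 5555 kb of the genome in all. Peaks were narrow, with a median width of 787 bp and quartiles of 681 and 897 bp, and no neighbouring peaks overlapped. The absence of replicates means that none of the values below has an error between cultures.

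Peak strength, as given by the authors' peak caller, spanned a wide range. The score ran from 50.03 to 1955.87, with a median of 109.54 and quartiles of 70.6 and 192. Of the 6792 peaks, 3733 (55.0%) had a score of at least 100, 1602 (23.6%) at least 200, 229 (3.37%) at least 500 and 16 (0.236%) at least 1000. At the other end, 915 peaks (13.5%) scored under 60, close to the lowest value in the list, so the number of peaks depended on where the caller's threshold was placed. Higher-scoring peaks were also wider. Across peaks, which are not independent replicates, Spearman's rho between width and score was 0.51.

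The highest-scoring region lay on chromosome 5, from 113585117 to 113586761, with a score of 1955.87 and a width of 1645 bp. It was followed by a 1237-bp peak on chromosome 16, from 11068218 to 11069454, with a score of 1752.32. The next were a peak on chromosome 10 from 80791452 to 80792832, which scored 1703.61, and a peak on chromosome 19 from 18680628 to 18681745, which scored 1547.5. The other peaks among the top 10 scored between 1138.25 and 1216.88. Among them, chromosome 7 held the peak from 31195849 to 31196992 and the peak from 71063682 to 71064941. Chromosome 2 held that from 35851814 to 35853053. The remaining 3 were on chromosome 11, from 21543940 to 21544783, from 74768038 to 74769244 and from 117169279 to 117170319. The genes at these positions were not identified here, because the gene table used here describes another genome build.

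Runx1 peaks were found on all 19 autosomes and on X, at very different densities. Chromosome 11 had the highest density, 4.55 peaks per Mb (95% interval 4.18 to 4.95, 539 peaks), followed by chromosome 19 with 4.27 per Mb (3.75 to 4.84, 247 peaks). Among autosomes, chromosomes 13, 18 and 3 had the lowest, 1.83 (1.59 to 2.09, 213 peaks), 1.86 (1.58 to 2.17, 158 peaks) and 1.90 peaks per Mb (1.69 to 2.14, 283 peaks). The intervals of these 3 chromosomes did not meet those of chromosomes 11 and 19. Chromosome 2 held the largest number, 551 peaks, at 3.09 per Mb.

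The X chromosome carried far fewer Runx1 peaks than any autosome. Its 45 peaks were 0.663% of the list (Wilson 95% interval 0.496 to 0.885%) and gave 0.287 peaks per Mb (0.210 to 0.384). The autosomes together had 6744 peaks and 2.83 per Mb (2.77 to 2.90), so the autosomal density was 9.87 times that of X (exact 95% interval 7.37 to 13.5). The highest score on X was 372.37. The median score was 98.3 on X (bootstrap 95% interval 78.1 to 130) and 109.64 on the autosomes, a value within the interval of X. No interval was computed for the difference between these medians. X peaks were narrower, with a median width of 618 bp against 788 bp. The list held 0 peaks on Y and 0 on the mitochondrial genome. A further 3 peaks lay on unplaced contigs, with scores of 71.72, 97.73 and 131.81.

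**Figure D1:**
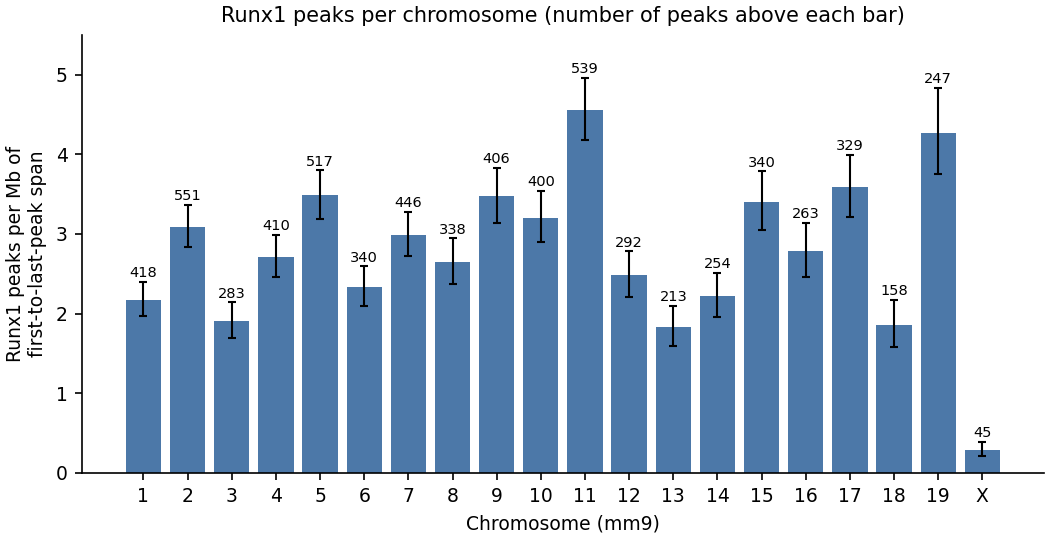
Runx1 peaks per Mb on each chromosome (y axis, from 0), over the span between the first and the last peak, for chromosomes 1 to 19 and X of mm9 (x axis). Bars are densities, lines are exact Poisson 95% intervals and the numbers are peaks; X stands at 0.287 per Mb, below the lowest autosome, chromosome 13, at 1.83.

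Runx1 peaks were grouped along the chromosomes. Neighbouring peak midpoints were a median of 72.7 kb apart, against 237 kb (230.5 to 243) when the same number of peaks was placed uniformly. In all, 1521 peaks (22.4%) lay in 417 clusters of 3 or more with neighbours within 20 kb, whereas 1000 uniform placements gave a mean of 22.6 clusters and 40 at most. The observed number was 18.5 times that mean. It was 3.45 times the mean of 121 clusters found when each peak was redrawn within its own stretch of 1 Mb, as described below. Of the clusters, 265 held 3 peaks, 90 held 4 and 62 held 5 or more. A further 825 pairs of peaks lay within 20 kb, and 3618 peaks (53.3%) had no neighbour at that distance. The uniform comparison did not leave out assembly gaps or sequence to which reads cannot be mapped, and the number of clusters fell to 148 when only peaks with a score of at least 100 were counted, against a mean of 4.04 in uniform placements of those peaks.

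**Figure D2:**
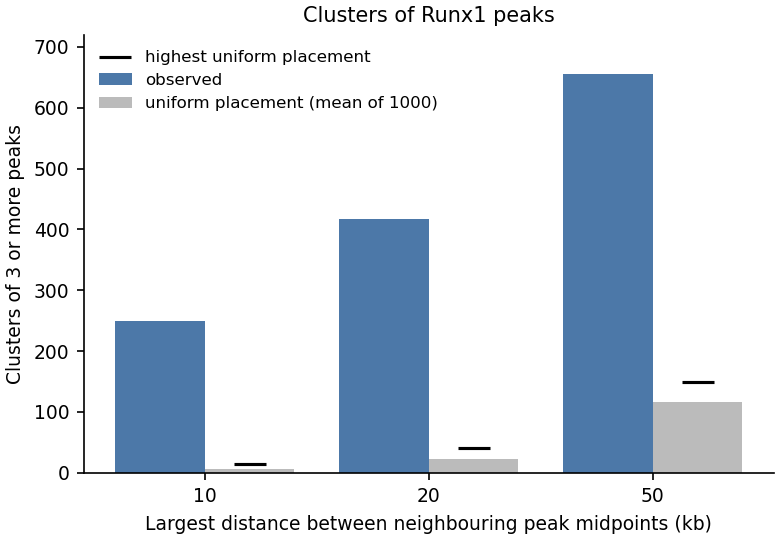
Number of clusters of 3 or more Runx1 peaks (y axis, from 0) for neighbour distances of 10, 20 and 50 kb (x axis), observed (blue) and as the mean of 1000 uniform placements (grey), with the highest placement as a black line. The 249, 417 and 656 observed clusters exceed the highest placements of 15, 40 and 149.

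The largest cluster comprised 11 peaks over 70.0 kb of chromosome 10, from 79340364 to 79410321, with scores between 62.3 and 743.22. Several of its intervals lay within 500 bp of the next. Peaks ending at 79343218, 79357642, 79359257 and 79360206 were followed by peaks starting at 79343629, 79357736, 79359362 and 79360226. A cluster of 10 peaks spanned 80.9 kb of chromosome 7, from 132698765 to 132779623, with a highest score of 887.8. In it, only the peaks ending at 132737229 and starting at 132737232 lay that close. Merging within 500 bp would leave more intervals in this chromosome 7 cluster than in that on chromosome 10. The size and rank of the chromosome 10 cluster thus depend on counting each interval separately. There were 4 clusters of 8 peaks. The 3 of these with the highest scores lay on chromosome 7 from 71041003 to 71085073, on chromosome 5 from 125487466 to 125537264 and again on chromosome 7 from 16742557 to 16793438. Their highest scores were 1160.48, 1026.89 and 522.24. In the chromosome 5 cluster, peaks ending at 125531308 and 125531912 were followed within 500 bp by peaks starting at 125531383 and 125532227. Its size therefore also depends on counting each interval separately. In each of the 5 clusters, strong and weak peaks stood side by side: the lowest score within a cluster was between 55.29 and 90.22. Of the 10 highest-scoring peaks in the list, 6 lay in a cluster, including the chromosome 5 peak that ranked first, which belonged to a cluster of 6.

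**Figure D3:**
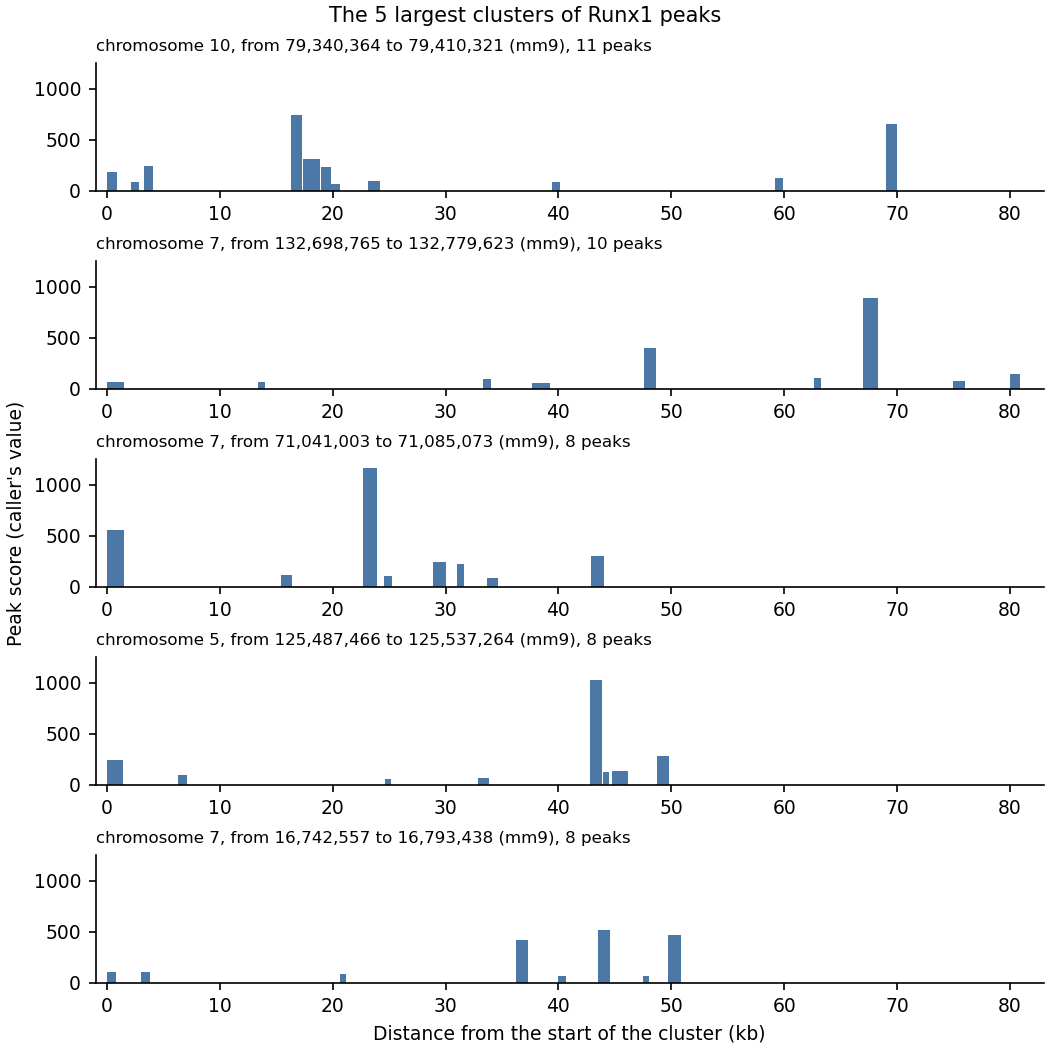
The 5 largest clusters of Runx1 peaks, one per panel, with distance from the cluster's start in kb (x axis, mm9) and the caller's peak score (y axis, from 0); each bar is 1 peak drawn to its width. Scores within the chromosome 10 cluster at the top range from 62.3 to 743.22 over 70.0 kb.

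On a broader scale, Runx1 peaks left large parts of the genome empty. Of 2557 stretches of 1 Mb between the first and last peaks of the chromosomes, 1048 (41.0%) held no peak, whereas uniform placements left 304 empty (95% range 283 to 326). The 311 most densely occupied stretches (12.2%) held 50% of the peaks, and 161 stretches had 10 or more peaks each, 2199 in all. The densest was the stretch of chromosome 9 from 57000001 to 58000000, with 26 peaks. Next were 3 stretches with 25 peaks, a neighbouring pair on chromosome 10 between 79000001 and 81000000 and 1 on chromosome 5 from 125000001 to 126000000. The 5 longest intervals without a peak were all on X, the longest measuring 22.2 Mb from 46428770 to 68617591. The longest on an autosome measured 12.1 Mb, on chromosome 6 from 54787274 to 66840370.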

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

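The low peak density of X and the excess of clusters over uniform placement held under each alternative run for them (other cluster distances do not bear on X), while the numbers themselves moved with the score threshold. With a score of at least 100 the list held 3733 peaks and 148 clusters, and the upper part of the list by score held 3397 peaks and 125 clusters. By construction the median score rose with them, from 109.54 to 181.92 and 192.33. Neighbour distances of 10 and 50 kb gave 249 and 656 clusters, and merging intervals within 2 kb, chosen after seeing the data, gave 271. A score threshold leaves fewer peaks, and another distance changes what counts as a cluster. Merging also joins close intervals of the same cluster. After merging within 2 kb the ratio of observed clusters to the uniform mean was 15.4, against 18.5 in the full list. The ratio of observed clusters to the uniform mean lay between 5.64 (50 kb) and 42.1 (10 kb), and the observed number exceeded the highest placement in 8 of 8 settings. Among these, the setting with chromosomes 1 to 19 and X alone is the same comparison as the full list. All settings were compared with uniform placement only, which does not keep differences in density between stretches of 1 Mb. The X-to-autosome ratio of peak density, 0.101 in the full list, was 0.0901 at a score of at least 100 and 0.0900 in the upper part of the list, and 0.105 and 0.110 after merging within 500 bp and 2 kb, both run for this ratio after seeing the data. Leaving out the 3 peaks on unplaced contigs, the 1 peak wider than 5 kb, or merging intervals within 500 bp (6579 peaks, 356 clusters) changed these values by less than 1.5 times. The 3 contig peaks enter neither the clusters nor the X ratio, so leaving them out could not change those. No replicate could be left out, since each arm had 1 library. The alternatives for promoters, gene parts, motifs, repeats and gene lists were not run, because they need the sequence or annotation of mm9. Without read numbers, the depth behind weak and missing peaks is unknown.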

Other observations

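All tests in this part were chosen after the peak list had been examined. The tests of gene number and of a single X copy were chosen after the result they bear on had been seen, and those of joined intervals, of density at 1 Mb and of width at equal score before theirs. Autosomes with more genes carried more Runx1 peaks. Across the 19 autosomes, the number of peaks and the number of protein-coding genes in the GRCm38.p6 gene table had Pearson's r = 0.84 and Spearman's rho = 0.89. For both, the permutation p was 1e-05, the smallest that 100000 permutations can give, and 3e-05 after Benjamini-Hochberg adjustment over 3 relations. The number of peaks also followed the span of the chromosome (r = 0.62, p = 0.0044, adjusted p = 0.0044; rho = 0.72, p = 0.00076, adjusted p = 0.00076, permutation tests). At equal span the relation with gene number remained (r = 0.74, permutation p = 0.00024, adjusted p = 0.00036; rho = 0.82, p = 5e-05, adjusted p = 7.5e-05). Without the 2 chromosomes farthest from the median on the x axis, the 3 values of r were 0.89, 0.63 and 0.77. Chromosomes are not replicates, and the relation describes this list.

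Peaks in clusters scored higher than isolated ones. The median score was 129 for peaks in clusters of 3 or more and 99.8 for peaks with no neighbour within 20 kb, a difference of 29.4 score units (95% interval 21.7 to 39.5, bootstrap over 1509 stretches of 1 Mb). Since wider peaks score higher, the medians were also compared within 4 equal-sized groups of peaks by width. Clustered peaks had the higher median in each of the 4 groups, by 5.63, 13.3, 23.1 and 28.9 from the narrowest to the widest. Each difference was smaller than the 29.4 found without grouping by width. The widest group ran up to 6165 bp, so widths were not equal within it. No interval was computed for these differences. Among the 100 highest-scoring peaks, 37 lay in clusters (Wilson 95% interval 28.2 to 46.8%), against 22.4% of all peaks.

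The grouping of peaks was weighed against technical explanations. The first was that the whole excess came from single bound regions reported as several intervals within 2 kb of each other. Joining intervals within 2 kb would then have brought the number of clusters into the range of uniform placement. After joining, 6260 intervals remained and formed 271 clusters, down from 417, against at most 33 in 1000 uniform placements. Splitting within 2 kb may thus account for part of the number of clusters, but not for the whole excess over uniform placement. How much of the excess it made cannot be told from this comparison. Unequal density at 1 Mb alone, tested below, gave a mean of 121 clusters, above the highest uniform placement of 40 for the full list. Splitting over more than 2 kb was not tested. If the grouping came only from unequal peak density between stretches of 1 Mb, which also takes up large assembly gaps and broad differences in copy number, redrawing each peak within its own stretch would have kept it. Such draws gave a mean of 121 clusters and at most 153, against the 417 observed, which was 3.45 times that mean. Density at that scale may therefore account for part of the excess but not for all of it. The joined intervals were not redrawn within stretches of 1 Mb, so splitting and density acting together were not tested. Uneven mappability below 1 Mb was not tested, and no biological explanation was tested.

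For the low number of peaks on X, fewer genes alone do not account for the pattern: X had 4.66 peaks per 100 protein-coding genes (95% interval 3.40 to 6.23), against 22.0 (19.98 to 24.11) on chromosome 7, the lowest autosome, and 32.6 over all autosomes. A single X copy is open, since the labels do not give the sex or karyotype of the cells. At the autosomal density X would have had 444 peaks. If one copy halved each score, 244 X peaks would be expected, from the 54.9% of autosomal peaks with at least 2 times the lowest score, and 45 were found. The 45 found lie below the 244, so under this assumption a halved score alone would not make X peaks this few. The 244 rests on an assumed relation between copies and score, so a copy-number effect cannot be told apart from other causes. Lower mappability of X was not tested.

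Peaks on X were narrower than their scores account for. The median width of 618 bp lay below the lowest of 10000 sets of autosomal peaks matched on score, whose medians averaged 769 bp (95% range 715 to 818, lowest 669). Lower scores of the X peaks are therefore argued against as the cause, and no other explanation was tested. A single wide peak stood apart on chromosome 17, from 39979711 to 39985875. It was 6165 bp wide with a score of only 64.74, while the next widest, on chromosome 5 from 121027757 to 121030534, measured 2778 bp and scored 189.86. Whether the chromosome 17 peak covers sequence present in many copies, such as ribosomal DNA, was not tested, since mm9 sequence was not used here. Reads from all copies would then pile up at one place, so its width and score are not read as a measure of Runx1 binding.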
